A study of Mus musculus with 44 samples.

How the data were processed

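Expression was measured on 44 Affymetrix Mouse 430 2.0 arrays, 1 per sample, from CH12.LX cells plated at 100000 cells per ml. The deposited values are signal intensities on a linear scale, made with GCOS 1.0 per the submitters' processing notes. Each deposited column has a mean signal of 500.0 after the lowest and highest 2% of values are left out, so the values had been scaled array by array before deposit. Other steps of that processing are not given in the sources used here. One column per sample was read through its sample identifier, and samples were grouped by treatment and time as the labels give them.

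The column medians of log2(value + 16) spanned 0.91, above the limit of 0.2 set beforehand, so the linear values were quantile normalized and then turned into log2(value + 16), whose lowest possible value is 4. Of 45101 probe sets, 64 controls were left out. In the annotation table used, 34945 of the others have 1 gene symbol, 932 have several and 9160 are not named; 34741 symbols were matched by gene identifier to the GRCm38.p6 gene table, which changed 0 of them. No coordinates are given, since no genome build goes with the array values. Each gene was represented by the probe set with the highest mean among those with 1 symbol, and no name was taken from a probe set with several. Genes whose highest group mean lay above the median of all values (6.21) were kept, which left 11970 of 18193 genes. Signals of different probe sets were not compared with each other.

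Tests were run with limma 3.58.1 in R 4.3.3: 1 fit of 11 group means over all arrays, empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment per comparison, with an adjusted p of 0.05 as the threshold. The comparisons were TCDD against vehicle at each of 5 times, vehicle at each of 5 times against untreated cells, and an F test of 4 interaction contrasts. P-values measure the spread between cultures of 1 cell line handled on separate days. Per the series' design text, same-numbered replicates share a day, so the numbers pair the samples. Same-numbered arrays of different groups had deviations from their group means that correlated with a median r of 0.18, against -0.065 for differently numbered arrays, and in 18 of 20 pairs of TCDD and vehicle arrays of the same time r was above 0.1. The fit without the day was fixed as the main one. It leaves differences between days in the spread, so a gene not called in it may be called with the day as a block. The fit with the replicate number as a block is given where it moves a count by over 1.5 times.

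The 22 gene lists and 6 lists of cell type markers were fixed before the data were examined. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of 220 pairs of list and comparison, 83 were called, and 38 of these with an estimated correlation too. Marker lists were read as levels and counts only. Ighm, Ighmbp2, Iglon5 and the single genes from the marker and reference lists were named after their values were seen. The other genes named in the text follow a rule fixed beforehand: 14 genes named whatever their values; for TCDD, the 4 largest changes per time and direction among genes past the threshold and changed the same way in all 4 same-day pairs; for vehicle cells at 8 and 48 h, the 6 largest per direction whose 4 arrays lie apart from the 4 untreated arrays; up to 4 called members of each list described; and the 6 genes with the smallest interaction p, 1 of which is not reported here. The rule skipped 5 unapproved symbols.

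The scripts were tested on simulated data with the real overall mean and residual spread of each gene and no time course. Noise and day shifts were drawn for each gene on its own, so the simulated genes were uncorrelated. The day shifts were added to spreads that already held the real differences between days. For TCDD against vehicle at 24 h over 11970 genes, 56% of genes changed 1.5-fold were recovered, 82% of those changed 2-fold, 92% at 3-fold and 96% at 4-fold, and 0 unchanged genes were called. The interaction test recovered 22%, 60%, 78% and 84% at the same folds, with 3 unchanged genes called. The list test called the 1 list shifted by 0.5 and 0 of the others. With uncorrelated genes, it cannot show how often lists of correlated genes would be called by mistake.

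Alternatives fixed beforehand were the day as a fixed or random block, only the arrays compared, no filter or a stricter filter, values as deposited, all probe sets, the mean of a gene's probe sets, pseudocounts of 1 and 64, an intensity trend, and leaving out each array and each day. Leaving out 4 arrays standing apart in technical measures (untreated 0 h replicates 3 and 4, DMSO 12 h replicate 4 and DMSO 48 h replicate 2) was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.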

Results

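The transcriptome of CH12.LX cells, a mouse B cell lymphoma line that can be driven towards antibody secretion, was measured over 48 h of activation with lipopolysaccharide (LPS), a bacterial cell wall component that stimulates B cells. The cells received either 10 nM of 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD), a persistent ligand of the aryl hydrocarbon receptor (AhR), or its vehicle, dimethyl sulfoxide (DMSO) at 0.01%. The 44 arrays fall into 11 groups of 4: untreated cells at 0 h, and vehicle and TCDD cells at 8, 12, 24, 36 and 48 h. Each of the 4 replicates was handled on its own day, so the replicate number stands for a day. On these arrays the precision is limited by the 4 arrays per group. Median array signals ran from 45.2 to 99.2, and replicate arrays correlated with r from 0.949 to 0.988 (median 0.980). A few arrays stood apart in technical measures. The 2 highest median signals were those of untreated 0 h replicate 4 (99.2) and DMSO 12 h replicate 4 (87.9). The transferrin receptor control probe sets had 3' to 5' log2 ratios of 3.34 in untreated 0 h replicate 3 and 3.12 in DMSO 48 h replicate 2, against a median of 1.19. Log2 values below are of signal plus 16, which understates the change of dim genes, and errors of log2 changes are standard errors from limma with 4 arrays per group.

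The first question was how activated vehicle cells differed from the untreated cells. Untreated cells were measured at 0 h only. Effects of LPS, of the vehicle and of time in culture can therefore not be told apart in these comparisons. At 8 h Il6, a cytokine, rose by 4.79 ± 0.30, Il1rn, the interleukin 1 receptor antagonist, by 4.17 ± 0.20, Zc3h12a, a ribonuclease that limits cytokine transcripts, by 3.93 ± 0.18, Sprr2d by 3.80 ± 0.34, Ptgs2, a prostaglandin synthase, by 3.60 ± 0.26 and Oasl1, an interferon-inducible gene, by 3.53 ± 0.36. Leaving aside 3 genes without an approved symbol, the genes with the largest falls were Sla (-3.44 ± 0.20), Bcl2l11, which encodes the pro-apoptotic protein Bim (-3.43 ± 0.26), Rasl10a (-3.23 ± 0.44), Rab30 (-3.11 ± 0.26), the immediate early gene Fosb (-3.06 ± 0.35) and the chemokine receptor Ackr3 (-2.94 ± 0.18). In all, 2944 of 11970 genes passed an adjusted p of 0.05 at 8 h, 1344 higher and 1600 lower. With only the arrays compared the count was 1518.

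Of the 25 measured members of the NF-kB and inflammatory list, 15 rose and 3 fell at 8 h (15 and 3 adjusted over the list alone), with Il6, Nfkbiz (2.86, and -0.40 on another probe set), Ccl5 (2.73) and Ccl3 (2.28) in front (adjusted p = 7.71e-08). Cholesterol synthesis genes fell almost as a block: 14 of 15 were lower (14 adjusted over the list alone; adjusted p = 1.31e-12 for the list), among them Hmgcs1 (-1.74), Msmo1 (-1.53), Insig1 (-1.51) and Cyp51 (-1.36). B cell identity genes were lower in 9 of 16 cases and higher in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.000175 for the list), with falls of Ets1 (-2.07), Cd22 (-1.98), Spib (-1.40) and Cd79b (-1.31). Genes of the unfolded protein response and secretion were lower in 12 of 26 cases (13 adjusted over the list alone; adjusted p = 2.49e-06 for the list), with Ero1b (-1.39), Syvn1 (-1.09), Herpud1 (-1.05) and Sec24d (-0.86) as the largest falls. The AhR target list was higher already in vehicle cells, with 4 of 7 members up (4 adjusted over the list alone; adjusted p = 0.003 for the list): Cyp1a1 by 2.15 ± 0.19, Cyp1b1 by 2.01 ± 0.34, Ahrr by 0.54 ± 0.20 and Tiparp by 0.42 ± 0.10. On other probe sets the change of Cyp1b1 at 8 h was 0.50 and -0.10, and neither was called. Cyp1a1 was also higher at 12 h (2.40 ± 0.19), and its change was 0.10 ± 0.19 at 24 h (adjusted p = 0.784). The call of Ahrr at 8 h was lost on the values as deposited and without the 4 arrays standing apart. Calls were lost without replicate 2 for Ahrr (0.48) and Tiparp (0.32), without replicate 3 for Ahrr (0.62) and without replicate 4 for Ahrr (0.30).

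Several lists were called at 8 h with the preset correlation only. Interferon response genes rose in 10 of 19 cases (10 adjusted over the list alone), led by Oasl1, Usp18 (2.69), Cxcl10 (2.03) and Rtp4 (1.46), with a adjusted p of 2.85e-07 for the list and an adjusted p = 0.0914 with an estimated correlation. MHC class II presentation genes fell in 8 of 11 cases (8 adjusted over the list alone), among them H2-Ob (-1.32), Ifi30 (-0.72), H2-DMb2 (-0.69) and H2-DMa (-0.66); the adjusted p was 0.188 with an estimated correlation. Integrated stress response genes fell in 8 of 13 cases (8 adjusted over the list alone), with Trib3 (-1.74), Chac1 (-1.34), Slc7a11 (-0.85) and Ddit3 (-0.70), and an adjusted p = 0.157 with an estimated correlation. Of 19 genes of MYC and ribosome biogenesis, 6 rose (6 adjusted over the list alone), with Polr1b (0.50), Nolc1 (0.41), Nop14 (0.33) and Nop56 (0.32), and an adjusted p = 0.157 with an estimated correlation. TGF-beta signalling genes fell in 6 of 14 cases (6 adjusted over the list alone), with Tgfbr2 (-1.31), Tgfbr1 (-1.25), Id3 (-1.21) and Id2 (-0.94), and an adjusted p = 0.082 with an estimated correlation; other probe sets of Tgfbr1 were not lower. Nop14, Chac1, Ddit3, H2-DMb2 and H2-DMa lost their calls without the 4 arrays standing apart. Calls were lost without replicate 1 for Slc7a11 (-0.80), Rtp4 (0.89), Nop14 (0.33) and Nop56 (0.25), without replicate 2 for Slc7a11 (-0.69), H2-DMb2 (-0.74), H2-DMa (-0.60), Rtp4 (1.30) and Id2 (-0.92), without replicate 3 for Slc7a11 (-0.83), Ddit3 (-0.64) and Nop14 (0.33) and without replicate 4 for Ddit3 (-0.68), H2-DMb2 (-0.56), H2-DMa (-0.60) and Nop14 (0.27).

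At 48 h the vehicle cells differed from the untreated cells in 5255 genes, 2803 higher and 2452 lower. With only the arrays compared the count was 3443. The largest rises were those of Nupr1, a stress-induced gene (7.10 ± 0.58), Il6 (6.09 ± 0.30), the chemokine Ccl5 (4.92 ± 0.43), Fgf21, a hormone gene induced by amino acid and endoplasmic reticulum stress (4.71 ± 0.28), Smtnl1 (3.81 ± 0.35) and Matn1 (3.81 ± 0.34). Leaving aside 1 gene without an approved symbol, the largest falls were those of Tnfsf14 (-5.00 ± 0.27), Ackr3 (-4.36 ± 0.18), Nxpe2 (-4.28 ± 0.40), Aff3 (-3.84 ± 0.16), the immediate early gene Egr1 (-3.82 ± 0.39) and Ltb, which encodes lymphotoxin beta (-3.69 ± 0.28). Another probe set of Aff3 was not lower. At 12, 24 and 36 h the counts were 2968 (1311 higher, 1657 lower), 2362 (1124 higher, 1238 lower) and 3748 (1847 higher, 1901 lower). With only the arrays compared they were 1310, 1214 and 2063. The 5 vehicle comparisons share the arrays of the untreated cells, so their overlap was not read as a shared effect.

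The plasma cell programme was higher at 48 h, with 11 of 14 members up (11 adjusted over the list alone; adjusted p = 1.25e-05 for the list). Prdm1, which encodes the repressor Blimp-1 that drives plasma cell differentiation, rose by 2.18 ± 0.14, Fkbp11 by 2.10 ± 0.10, Sdc1, which encodes the plasma cell surface protein syndecan-1, by 1.20 ± 0.25 and Irf4 by 0.94 ± 0.11. Prdm1 was higher from 8 h (1.98 ± 0.14) and reached 2.82 ± 0.14 at 36 h. Jchain, another member of the list, went the other way early. Its log2 signals ran from 10.25 to 10.70 in untreated cells. In vehicle cells they ran from 9.25 to 9.67 at 8 h and from 8.66 to 9.50 at 12 h. At 48 h they ran from 9.93 to 11.45, which overlaps the untreated range. B cell identity genes were lower in 10 of 16 cases (10 adjusted over the list alone, adjusted p = 0.000123 for the list). Among them were Ms4a1 (-3.07), Spib (-2.28), Cd22 (-2.17) and Bach2, a repressor of plasma cell differentiation (-2.16 ± 0.39). The untreated signals of Bach2 were 8.20 and 8.28 in replicates 1 and 2 but 6.11 and 6.44 in replicates 3 and 4. Vehicle signals at 48 h ran from 4.69 to 5.62, so the size of its fall depends on the untreated arrays used. Pax5, the B cell identity factor, had a change of -0.34 ± 0.30 and did not pass (adjusted p = 0.379). Its log2 signals ran from 6.26 to 7.08 in untreated cells and from 6.10 to 6.86 in vehicle cells at 48 h. The lowest of these lie at the filter on dim genes, so the missing call does not show that Pax5 was unchanged. Bcl6 stayed below that filter, with group means from 4.82 to 5.87. The genes of the unfolded protein response and secretion, lower at 8 and 12 h, were higher at 24 h (12 of 26 up, 1 down), 36 h (17 up) and 48 h (15 up, 1 down; 16 and 1 adjusted over the list alone; adjusted p = 5.58e-06 for the list), led by Herpud1 (1.64), Derl3 (1.63), Sel1l (1.40) and Sec24d (1.31). Adjusted over the list alone, the counts were 13 up and 2 down at 24 h and 20 up at 36 h. Xbp1, the transcription factor of that response, moved from -1.13 ± 0.07 at 8 h to 0.56 ± 0.07 at 48 h. Integrated stress response genes rose in 12 of 13 cases (12 adjusted over the list alone; adjusted p = 4.72e-07 for the list), with Ddit3 (3.61), Chac1 (3.59), Trib3 (2.91) and Ddit4 (2.80). Ahr itself was lower by 24 h (-2.00 ± 0.16) and at 48 h (-2.58 ± 0.16).

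The lists for G1/S and for MYC were lower at 48 h, and that for mitosis was not. Of 24 genes of G1/S and DNA replication, 19 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 1.25e-05 for the list), with Tyms (-1.01), Ung (-0.94), Ccne2 (-0.80) and Mcm3 (-0.78); the other probe sets of Tyms were not lower. In the G2/M and mitosis list 7 of 24 genes rose and 1 fell at 48 h (7 and 1 adjusted over the list alone; adjusted p = 0.106 for the list). Among MYC and ribosome biogenesis genes 16 of 19 fell (16 adjusted over the list alone; adjusted p = 1.28e-06 for the list), with Rrp12 (-1.24), Polr1b (-1.14), Nop58 (-0.89) and Cad (-0.83). Interferon genes were up in 14 of 19 cases and down in 1 (14 and 1 adjusted over the list alone), with Oasl1 (3.60), Usp18 (3.12), Rtp4 (2.54) and Oasl2 (2.26), and an adjusted p = 0.111 with an estimated correlation. The p53 targets rose in 11 of 16 cases (11 adjusted over the list alone), with Gadd45a (2.61), Pmaip1 (2.22), Fas (1.73) and Cdkn1a (1.70), and an adjusted p = 0.155 with an estimated correlation. Among CDK inhibitors and D cyclins 6 of 10 rose and 2 fell (6 and 2 adjusted over the list alone), with Ccnd2 (1.73), Cdkn1a, Cdkn1b (1.23) and Cdkn2d (0.99), and an adjusted p = 0.089 with an estimated correlation. Ccnd2 promotes entry into the cycle, whereas Cdkn1a, Cdkn1b and Cdkn2d inhibit cyclin-dependent kinases. The NF-kB list had 12 of 25 members up and 4 down (13 and 6 adjusted over the list alone), with Il6, Ccl5, Ltb (-3.69) and Nfkbiz (3.30), and an adjusted p = 0.127 with an estimated correlation; another probe set of Nfkbiz was called lower at 48 h (-0.93). A call was lost without replicate 2 for Ccne2 (-0.60).

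Further lists were called at 48 h with the preset correlation and lost with an estimated one. MHC class II presentation genes fell in 6 of 11 cases and rose in 1 (6 and 1 adjusted over the list alone), with H2-DMb2 (-1.33), H2-Ab1 (-1.17), Ifi30 (-0.78) and H2-DMa (-0.72), and an adjusted p = 0.382 with an estimated correlation. Genes of the NRF2 oxidative stress response fell in 6 of 15 cases and rose in 3 (7 and 3 adjusted over the list alone), with Slc7a11 (1.84), Gclc (-1.82), Gsta4 (-1.61) and Gclm (-1.10), and an adjusted p = 0.089 with an estimated correlation. TGF-beta signalling genes fell in 7 of 14 cases and rose in 1 (7 and 1 adjusted over the list alone), with Id2 (-1.35), Tgfbr1 (-1.34), Smad2 (-1.09) and Tgfb1 (-0.99), and an adjusted p = 0.0897 with an estimated correlation. H2-DMa and Tgfb1 lost their calls without the 4 arrays standing apart. Calls were lost without replicate 2 for H2-DMa (-0.67), without replicate 3 for Tgfb1 (-0.81) and without replicate 4 for H2-DMa (-0.58).

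**Figure D1:**
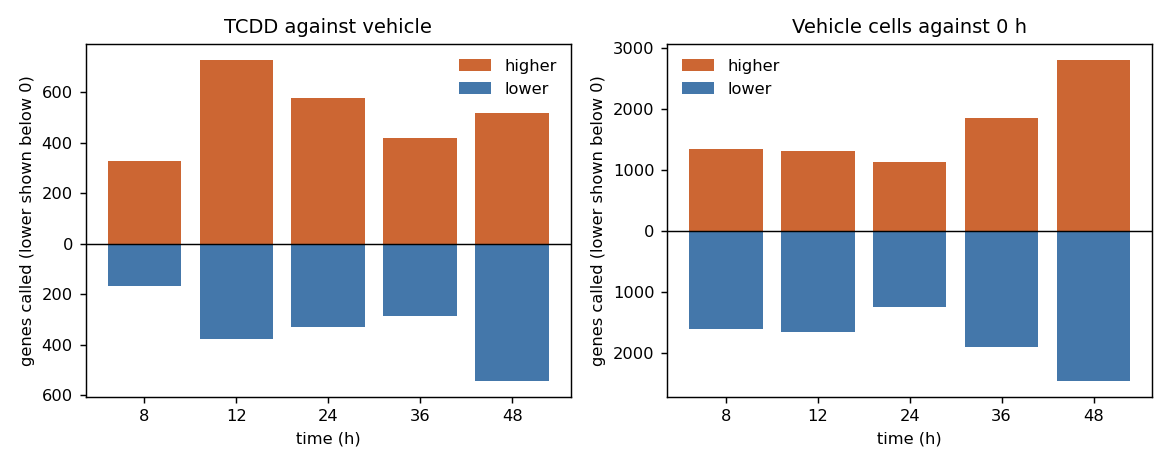
Number of genes past an adjusted p of 0.05 (y axis, higher above 0 and lower below 0) by time in h (x axis), for TCDD against vehicle (left) and for vehicle cells against untreated cells (right), with 4 arrays per group. The TCDD counts run from 497 at 8 h to 1103 at 12 h, and the vehicle counts from 2362 at 24 h to 5255 at 48 h.

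The second question was what TCDD changed against vehicle at the same time. Targets of the AhR were higher at each time. Cyp1a1, a cytochrome P450 gene that the receptor activates, was higher by 5.21 ± 0.19, 4.94 ± 0.19, 6.01 ± 0.19, 5.51 ± 0.19 and 4.50 ± 0.19 at 8, 12, 24, 36 and 48 h. Its level at 8 h was 13.37 ± 0.06 (SD, n = 4) with TCDD and 8.16 ± 0.25 in vehicle cells. Cyp1b1 was higher by 1.51 ± 0.34 at 8 h and 3.33 ± 0.34 at 36 h, Ahrr, which encodes a repressor of the receptor, by 1.61 ± 0.20 to 2.03 ± 0.20, and Tiparp, a target that also restrains the receptor, by 1.18 ± 0.10 to 1.58 ± 0.10. Nqo1, a quinone reductase, was higher at 8, 12 and 24 h (0.98 ± 0.25, 1.11 ± 0.25 and 0.94 ± 0.25). Adjusted over all genes, its changes of 0.67 ± 0.25 and 0.71 ± 0.25 at 36 and 48 h passed only with the replicate block (adjusted p = 0.000702 and 0.000254). Of the 7 measured targets, 5, 6, 5, 4 and 4 rose at the 5 times (7, 6, 5, 6 and 5 adjusted over the list alone), and none fell. The list test gave adjusted p-values from 8.51e-20 at 8 h to 1.24e-12 at 48 h, and the largest with an estimated correlation was 8.41e-07. One other probe set of Cyp1b1 was not higher at 24 h. Ahr was lower at 12 h only among the 5 tests (-0.65 ± 0.16, adjusted p = 0.00458). At 8 h calls were lost without replicate 1 for Nqo1 (0.90), without replicate 2 for Cyp1b1 (1.47) and Nqo1 (0.99) and without replicate 3 for Cyp1b1 (1.41) and Nqo1 (0.99). At 24 h a call was lost without replicate 2 for Nqo1 (0.83) and without replicate 3 for Nqo1 (1.01).

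At 8 h TCDD changed 497 genes, 329 higher and 168 lower. Beside Cyp1a1, the largest rises were those of Plet1 (3.82 ± 0.30), the protease inhibitor gene Spint1 (2.57 ± 0.28) and Vdr, the vitamin D receptor (2.55 ± 0.33). The cytokine genes Il6 (-1.66 ± 0.30) and Il4 (-1.47 ± 0.27) led the falls, followed by P3h2 (-1.37 ± 0.31) and Fhit (-1.33 ± 0.38), whose call was lost on the values as deposited. MYC and ribosome biogenesis genes fell in 2 of 19 cases (3 adjusted over the list alone), Myc by -0.68 ± 0.09 and Polr1b by -0.39 ± 0.10, with an adjusted p = 0.327 with an estimated correlation. With the replicate block the count was 1004, and with only the arrays compared 312. Without replicate 2 it was 236, and without replicate 3 it was 259. At this time calls were lost without replicate 1 for P3h2 (-1.30) and Polr1b (-0.33), without replicate 2 for Fhit (-1.23) and Polr1b (-0.40), without replicate 3 for Fhit (-1.19) and without replicate 4 for Fhit (-1.30) and Polr1b (-0.41).

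At 12 h 1103 genes differed, 727 higher and 376 lower. Plet1 was higher by 5.38 ± 0.30, Slfn1, a member of the Schlafen family, by 2.83 ± 0.40 and Ctla4, an inhibitory receptor gene best known from T cells, by 2.77 ± 0.21. Niban3 (-1.70 ± 0.13), Il6 (-1.55 ± 0.30), Il4 (-1.45 ± 0.27) and Ccl5 (-1.35 ± 0.43) fell, with 1 larger fall skipped for want of an approved symbol, and the call of Ccl5 was also lost on the values as deposited. Another probe set of Slfn1 was not higher at 12 or 48 h. Cyp2s1, another AhR target, rose by 2.38 ± 0.38. In the MYC and ribosome biogenesis list 6 of 19 genes fell (9 adjusted over the list alone), Myc by -0.47 ± 0.09, Polr1b by -0.41 ± 0.10, Nolc1 by -0.41 ± 0.10 and Pes1 by -0.30 ± 0.08, with an adjusted p of 7.61e-08 for the list and an adjusted p = 0.0234 with an estimated correlation. With the replicate block the count was 1950, and with only the arrays compared 401. Without replicates 2, 3 and 4 in turn it was 509, 714 and 640. Among the genes named here, calls were lost without replicate 1 for Ccl5 (-1.44) and Pes1 (-0.28), without replicate 2 for Ccl5 (-1.19), Polr1b (-0.39) and Pes1 (-0.31), without replicate 3 for Ccl5 (-1.48), Nolc1 (-0.39) and Pes1 (-0.27) and without replicate 4 for Ccl5 (-1.29) and Pes1 (-0.33).

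At 24 h 907 genes differed, 575 higher and 332 lower. Slfn1 (4.39 ± 0.40), the interferon-inducible gene Oasl2 (4.32 ± 0.32) and Plet1 (4.18 ± 0.30) followed Cyp1a1. The largest falls were those of Cd37, a tetraspanin of B cells (-2.13 ± 0.34), Zpbp2 (-1.54 ± 0.33), the fatty acid receptor Cd36 (-1.47 ± 0.23) and Epas1 (-1.40 ± 0.34). Other probe sets of Cd37 and Zpbp2 were not lower. Mitotic genes fell in 4 of 24 cases and rose in 1 (4 and 1 adjusted over the list alone), with Mki67 (-0.40), Nek2 (0.38), Aurka (-0.37) and Tpx2 (-0.31), and an adjusted p = 0.326 with an estimated correlation. Other probe sets of Aurka and Tpx2 were not lower. MYC and ribosome biogenesis genes fell in 2 of 19 cases (2 adjusted over the list alone), Pes1 (-0.35) and Ddx21 (-0.23), with an adjusted p = 0.326 with an estimated correlation; another probe set of Pes1 had a change of 0.026. Cholesterol synthesis genes fell in 2 of 15 cases (2 adjusted over the list alone), Dhcr7 (-0.50) and Idi1 (-0.43), with an adjusted p = 0.519 with an estimated correlation, and the call of Idi1 was lost on the values as deposited. With the replicate block the count was 1625. Without replicates 2, 3 and 4 in turn it was 483, 583 and 598. Leaving out single days ended calls without replicate 1 for Epas1 (-1.07), Mki67 (-0.36), Tpx2 (-0.28), Dhcr7 (-0.48), Pes1 (-0.28) and Ddx21 (-0.17), without replicate 2 for Mki67 (-0.42), Aurka (-0.37), Idi1 (-0.47) and Ddx21 (-0.21), without replicate 3 for Epas1 (-1.32), Mki67 (-0.41), Dhcr7 (-0.42), Idi1 (-0.38) and Ddx21 (-0.28) and without replicate 4 for Mki67 (-0.41), Aurka (-0.37), Tpx2 (-0.28), Dhcr7 (-0.53), Idi1 (-0.41) and Ddx21 (-0.24).

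At 36 h 705 genes differed, 418 higher and 287 lower. Plet1 (3.58 ± 0.30), Slfn1 (3.38 ± 0.40) and Cyp1b1 were the highest after Cyp1a1. Cd36 (-1.97 ± 0.23), the sialyltransferase genes St8sia4 (-1.73 ± 0.18) and St6gal1 (-1.58 ± 0.21) and the cell cycle regulator Rgcc (-1.71 ± 0.47) fell most. The plasma cell programme fell in 5 of 14 cases (6 adjusted over the list alone; adjusted p = 2.68e-06 for the list), with Cxcr4, a chemokine receptor (-1.16 ± 0.15), Prdm1 (-0.57 ± 0.14), Fkbp11 (-0.44 ± 0.10) and Creld2 (-0.30 ± 0.08). Genes of the unfolded protein response and secretion fell in 6 of 26 cases (7 adjusted over the list alone; adjusted p = 8.42e-07 for the list), with Sec24d (-0.63), Sel1l (-0.39), Ero1b (-0.36) and Dnajc3 (-0.32); the call of Ero1b was lost on the values as deposited. Mitotic genes fell in 1 of 24 cases and rose in 1 (3 and 1 adjusted over the list alone), Tpx2 (-0.28) and Nek2 (0.37), with an adjusted p = 0.247 with an estimated correlation, and another probe set of Nek2 was not higher. Glycolysis and hypoxia genes fell in 1 of 19 cases (1 adjusted over the list alone), Pgk1 (-0.24), with an adjusted p = 0.285 with an estimated correlation. MYC and ribosome biogenesis genes rose in 1 of 19 cases (2 adjusted over the list alone), Nop56 (0.31, not called on the values as deposited), with an adjusted p = 0.285 with an estimated correlation. With the replicate block the count was 1307, and with only the arrays compared 437. Without replicates 1, 2 and 3 in turn it was 469, 282 and 385. Fits without a day hold fewer arrays, so a lost call does not show that the day carried the change. Without replicate 1 calls were lost for Prdm1 (-0.56), Rgcc (-1.45), Creld2 (-0.28), Ero1b (-0.36), Dnajc3 (-0.29), Tpx2 (-0.29), Pgk1 (-0.20) and Nop56 (0.35). Without replicate 2 they were lost for Prdm1 (-0.53), Rgcc (-1.60), Fkbp11 (-0.45), Creld2 (-0.29), Sec24d (-0.63) and Sel1l (-0.39). Ero1b (-0.36), Dnajc3 (-0.30), Tpx2 (-0.33), Pgk1 (-0.22) and Nop56 (0.23) also lost theirs without replicate 2. Without replicate 3 calls were lost for Fkbp11 (-0.36), Sel1l (-0.41), Ero1b (-0.40) and Tpx2 (-0.23). Without replicate 4 they were lost for Rgcc (-1.78), Creld2 (-0.29), Sec24d (-0.63), Sel1l (-0.38) and Ero1b (-0.31). Dnajc3 (-0.35), Tpx2 (-0.28), Pgk1 (-0.25) and Nop56 (0.33) also lost theirs without replicate 4.

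At 48 h 1059 genes differed, 516 higher and 543 lower. Ifng, the interferon gamma gene, rose by 3.36 ± 0.32, Asb2 by 3.29 ± 0.17 and Slfn1 by 3.03 ± 0.40. Ifng and Asb2 were called higher at all 5 times, from 8 h on. The largest falls were those of the hypoxia-inducible gene Ankrd37 (-2.07 ± 0.50), Cd36 (-2.00 ± 0.23), Iffo2 (-1.91 ± 0.35) and St8sia4 (-1.56 ± 0.18). The plasma cell programme was lower in 5 of 14 cases (6 adjusted over the list alone; adjusted p = 0.00012 for the list), with Cxcr4 (-1.15), Sdc1 (-1.06 ± 0.25), Fkbp11 (-0.58) and Xbp1 (-0.39 ± 0.07). Genes of the unfolded protein response and secretion were lower in 10 of 26 cases (12 adjusted over the list alone; adjusted p = 3.9e-07 for the list), with Sec24d (-0.50), Herpud1 (-0.48), Sel1l (-0.48) and Dnajb9 (-0.48). Other probe sets of Fkbp11 and Sel1l were not lower. Jchain, which joins IgM and IgA multimers, had a change of -0.40 ± 0.33 and did not pass (adjusted p = 0.562, and 0.155 with the replicate block), although Jchain was lower with TCDD in all 4 same-day pairs at 48 h and also at 36 h (-0.48 ± 0.33, adjusted p = 0.549, and 0.106 with the replicate block). At 24 h Jchain was higher with TCDD in all 4 pairs (0.25 ± 0.33), also not called. None of the 12 measured members of the immunoglobulin list was called with TCDD at any of the 5 times, nor after adjustment over the list alone. With the replicate block Ighm, named after its values were seen, was lower at 36 h (-0.66, adjusted p = 0.000427) and at 48 h (-0.62, adjusted p = 0.000576), and without the 4 arrays standing apart 1 member was lower at 8 h and 1 at 48 h. That list was drawn by name pattern and includes Iglon5 and Ighmbp2, which encode no immunoglobulin chain. Integrated stress response genes fell in 2 of 13 cases (3 adjusted over the list alone), Ppp1r15a (-0.98) and Ddit4 (-0.73), with an adjusted p = 0.176 with an estimated correlation. Among G1/S genes, 1 of 24 rose (1 adjusted over the list alone), Ccne2 (0.87), with an adjusted p = 0.13 with an estimated correlation. MYC and ribosome biogenesis genes rose in 3 of 19 cases (3 adjusted over the list alone), Nop56 (0.33), Wdr43 (0.25) and Odc1 (0.23, not called on the values as deposited), with an adjusted p = 0.253 with an estimated correlation. The p53 targets fell in 1 of 16 cases (1 adjusted over the list alone), Bbc3 (-0.70, not called without the 4 arrays standing apart), with an adjusted p = 0.451 with an estimated correlation. With the replicate block the count was 1870, and with only the arrays compared 311. Without replicate 2 it was 451, and without replicate 3 it was 625. Calls were lost without replicate 1 for Sec24d (-0.44), Herpud1 (-0.44), Nop56 (0.29), Wdr43 (0.30), Odc1 (0.22) and Bbc3 (-0.68), without replicate 2 for Ankrd37 (-1.45), Herpud1 (-0.51), Sel1l (-0.38), Ppp1r15a (-0.80), Ddit4 (-0.60), Ccne2 (0.78), Odc1 (0.23) and Bbc3 (-0.63), without replicate 3 for Sdc1 (-0.76), Sec24d (-0.42), Herpud1 (-0.45), Ddit4 (-0.79), Nop56 (0.28), Wdr43 (0.19) and Odc1 (0.26) and without replicate 4 for Sec24d (-0.47), Herpud1 (-0.53), Nop56 (0.30), Wdr43 (0.20), Odc1 (0.23) and Bbc3 (-0.72).

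**Figure D2:**
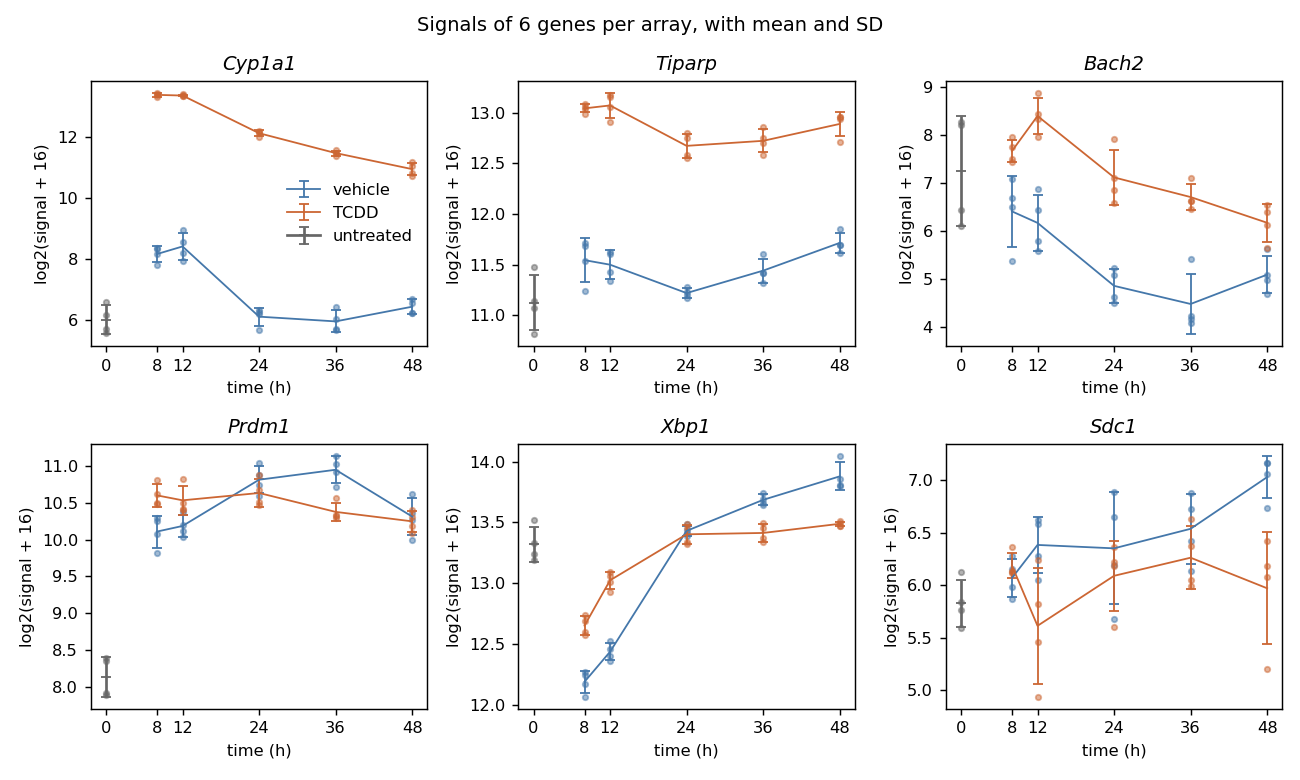
Log2(signal + 16) of 6 genes (y axes) by time in h (x axes) in untreated (grey), vehicle (blue) and TCDD cells (orange); points are single arrays, and lines and bars give the mean and SD of 4 arrays. Cyp1a1 at 8 h was 13.37 with TCDD and 8.16 in vehicle cells, and Xbp1 was above vehicle at 8 h (12.65 and 12.19) and below it at 48 h (13.49 and 13.88).

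Interferon response genes rose together with TCDD. At 12 h 14 of the 19 measured members were higher (18 adjusted over the list alone), with Ifit1 (2.31), Rtp4 (2.21), Oasl2 (2.00) and Ifit3 (1.84). At 24 h all 19 were higher (19 adjusted over the list alone), with a median log2 change of 2.21, and Oasl2 (4.32), Usp18 (3.72), Ifit3 (3.66) and Ifit1 (3.61) led. At 36 h 15 were higher (18 adjusted over the list alone), led by Oasl2 (2.52), Rsad2 (2.25), Usp18 (2.20) and Cxcl10 (2.05). At 48 h 11 were higher (14 adjusted over the list alone), led by Rsad2 (1.65), Oasl2 (1.60), Ifit2 (1.58) and Cxcl10 (1.50). The list p-values with an estimated correlation were 0.00801, 3.1e-06, 0.000169 and 0.0197 at 12, 24, 36 and 48 h. At 8 h 1 member, Gbp2, was called (0.74; 5 adjusted over the list alone), and the list's p of 0.000857 became an adjusted p = 0.59 with an estimated correlation. The list's effect was larger at 24 h than at 8 h by a median of 1.88 (adjusted p = 5.87e-50, and adjusted p = 9.29e-06 with an estimated correlation). The call of Gbp2 at 8 h was lost without replicate 1 (0.71), without replicate 2 (0.72) and without replicate 3 (0.81). The call of Rtp4 at 12 h was lost without replicate 2 (2.01).

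**Figure D3:**
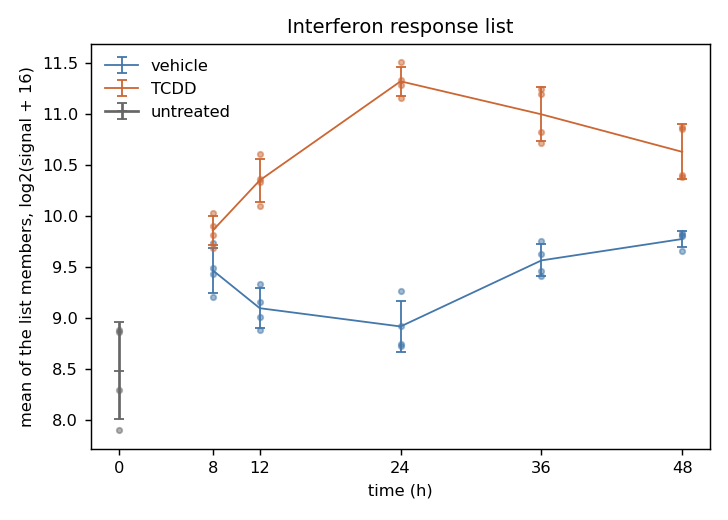
Mean log2(signal + 16) of the 19 measured interferon response genes (y axis) by time in h (x axis) in untreated (grey), vehicle (blue) and TCDD cells (orange); points are single arrays, and lines and bars give the mean and SD of 4 arrays. TCDD cells reached 11.32 at 24 h, when vehicle cells stood at 8.92.

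Markers of other cell types were read beside these lists, and the single genes named from the marker and reference lists were chosen after their values were seen. In the myeloid list Csf1r, the receptor for colony stimulating factor 1, was higher with TCDD at each time (1.58 ± 0.09 to 1.88 ± 0.09), Fcgr3 was higher at 8 and 12 h (1.02 and 1.06) and Adgre1 from 12 h on (0.70 to 0.94), while Cd68 was lower at 48 h (-0.60 ± 0.12). Of the 5 measured myeloid markers, 2, 3, 2, 2 and 2 rose at the 5 times (3, 3, 3, 2 and 2 adjusted over the list alone, and the same numbers with the replicate block). Gzma, a granzyme gene of cytotoxic cells, was higher from 12 h on and by 2.95 ± 0.31 at 24 h, and the other measured NK cell marker, Prf1, was not called over all genes (0.42 at 12 h, adjusted p = 0.0767). Adjusted over the list alone 1, 2, 2, 1 and 1 of the 2 NK cell markers rose at the 5 times, and with the replicate block Prf1 was called at 12 h (adjusted p = 0.0217). None of the 4 measured T cell markers was called over all genes with TCDD (1 higher at 48 h adjusted over the list alone, and 1 with the replicate block). Some abundant transcripts of other cells stayed below the filter of 6.21. Their highest group means were 6.08 for Lyz2, 4.98 for S100a8, 5.07 for S100a9, 5.97 for Cd3d and 4.86 for Cd4. Itgam (5.80), Csf3r (5.78), Ncr1 (5.43), Klrd1 (5.41) and Tcra (5.21) stayed below it too. Cd14 (6.62), Cd3g (6.58) and Cd3e (6.39) lay just above the filter. Some other members of the T, NK and myeloid lists lay well above it. Among them were Cd2 (11.05), Fcgr3 (10.75), Cd68 (10.67), Csf1r (10.64), Cd8a (9.38), Adgre1 (9.21) and Prf1 (8.76). In the stromal list, Lum was higher at 8 h (0.85 ± 0.24). No epithelial marker was called with TCDD (1 lower at 8 h adjusted over the list alone), and no erythroid marker passed the filter. Among 8 reference genes, Gusb was lower at 12, 24 and 48 h (-0.29, -0.33 and -0.31) and B2m was higher at 24 h (0.30).

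The third question was whether the effect of TCDD differed between times. The F test over the 4 differences from 8 h called 836 genes (1915 with the replicate block; 516, 255, 349 and 416 without replicates 1, 2, 3 and 4). Xbp1 had the smallest p (adjusted p = 5.13e-09): its TCDD effect was 0.46 ± 0.07 at 8 h, 0.59 ± 0.07 at 12 h, -0.028 ± 0.07 at 24 h, -0.27 ± 0.07 at 36 h and -0.39 ± 0.07 at 48 h. Stx5a, a syntaxin gene of Golgi traffic, went from 0.47 ± 0.08 at 8 h to -0.53 ± 0.08 at 48 h. The glycosyltransferase gene Mgat4a was higher at 8 h (1.00 ± 0.09) and not called at 48 h (-0.035 ± 0.09). St8sia4 went from 0.33 ± 0.18 to -1.56 ± 0.18, and Cyb561a3 from -0.33 ± 0.12 to 1.09 ± 0.12. The effect on Prdm1 also differed (adjusted p = 0.00121), from 0.49 ± 0.14 at 8 h to -0.57 ± 0.14 at 36 h and -0.065 ± 0.14 at 48 h, the last not called. For Bach2, which TCDD raised by 2.23 ± 0.39, 2.26 ± 0.39 and 2.23 ± 0.39 at 12, 24 and 36 h, a difference between times did not pass (adjusted p = 0.373), and another probe set of Bach2 was not higher at 12 or 36 h. The chosen probe set was also higher with TCDD in every same-day pair at 8 and 48 h. Its log2 signals were 7.45 to 7.97 against 5.37 to 7.09 in vehicle cells at 8 h. At 48 h they were 5.64 to 6.55 against 4.69 to 5.62. Irf4 (-0.41 ± 0.11) and Sdc1 (-0.77 ± 0.25) were lower at 12 h, and another probe set of Sdc1 was not. The signal of Irf4 was lower with TCDD in every same-day pair at each of the 5 times. Pax5 was called at none of the 5 times. Its log2 signals ran from 5.15 to 6.93 in vehicle cells and from 5.01 to 7.13 in TCDD cells. These lie around the filter on dim genes, so the missing calls do not show that Pax5 was unchanged. By list, the TCDD effect at 48 h was compared with that at 8 h. For the unfolded protein response and secretion the median difference in effect was -0.31 (adjusted p = 3.14e-07). For the plasma cell programme it was -0.33 (adjusted p = 0.0064). The effect differed the other way for MYC and ribosome biogenesis (0.23, adjusted p = 3.14e-07) and for G1/S genes (0.22, adjusted p = 4.25e-05). At 8 h a call was lost without replicate 1 for Prdm1 (0.53), without replicate 2 for Prdm1 (0.52) and without replicate 3 for Prdm1 (0.43). At 12 h calls were lost without replicate 1 for Sdc1 (-0.76), without replicate 2 for Sdc1 (-0.48), without replicate 3 for Irf4 (-0.38) and without replicate 4 for Irf4 (-0.29) and Sdc1 (-0.83). At 36 h calls were lost without replicate 1 for Prdm1 (-0.56), without replicate 2 for Prdm1 (-0.53) and Xbp1 (-0.26) and without replicate 3 for Xbp1 (-0.25).

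Over the 5 times 2422 genes were called with TCDD at least once and 1399 at exactly 1 time. The 96 genes higher at all 5 times and the 15 lower at all 5 come from comparisons of group means that share no arrays. The comparisons do share the days and 1 estimate of the spread per gene, so their lists are not independent. Between 24 and 36 h, 292 genes were higher at both times, where independent lists would share 20.1, and between 8 and 48 h 126 were, against 14.2. Opposite calls were made for 88 genes.

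**Figure D4:**
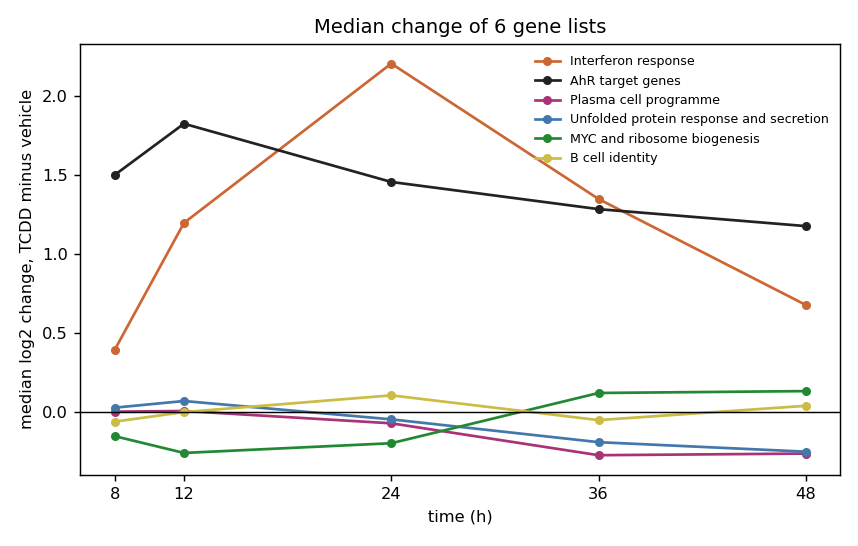
Median log2 change, TCDD minus vehicle (y axis), of the measured members of 6 gene lists by time in h (x axis), from group means of 4 arrays each; each line is a list. The interferon list peaks at 2.21 at 24 h, and the plasma cell and unfolded protein response lists end at -0.26 and -0.25 at 48 h.

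Last, the effect of TCDD was set against the vehicle time course. Across the 3748 genes called in vehicle cells at 36 h, the vehicle change and the TCDD effect at 48 h, which share no arrays, had a Spearman correlation of -0.24 across genes, which are not independent replicates. Of the 610 genes called in both comparisons, 443 changed in opposite directions. In the splits of the 8 arrays at 48 h into 4 and 4, 5 of 35 gave a correlation as large in size, so the correlation was not larger than other groupings of the same arrays give. The lists for AhR pathway components, immediate early genes, immunoglobulins and reference genes passed the list test in none of the 10 comparisons. Apoptosis regulators passed it once, in vehicle cells at 36 h, where 7 rose and 2 fell (7 and 2 adjusted over the list alone), with an adjusted p = 0.0744 with an estimated correlation.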

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

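The tests of the vehicle course, of mixed RNA and of other cell types below were chosen after the results they bear on had been seen; the tests of single days and of a wider response were written before. Of 209 groups of 4 arrays checked for 1 array far from the others, 12 were found, where chance gives about 10.45, so single cases are given as values only. Replicate 4 stood apart for Ahrr in DMSO 12 h (6.61, others 7.20 to 7.28) and TCDD 24 h (7.83, others 8.09 to 8.13), for Tiparp in TCDD 48 h (12.71, others 12.94 to 12.96), for Prdm1 in TCDD 36 h (10.57, others 10.30 to 10.33) and for Bach2 in DMSO 36 h (5.42, others 4.10 to 4.24). Replicate 2 stood apart for Sdc1 in TCDD 8 h (6.36, others 6.11 to 6.14). Median array signals stood apart in DMSO 12 h replicate 4 (87.9, others 47.6 to 54.1) and DMSO 36 h replicate 3 (76.4, others 54.6 to 57.4). Transferrin receptor 3' to 5' log2 ratios stood apart in untreated 0 h replicate 3 (3.34, others 1.25 to 1.42), DMSO 48 h replicate 2 (3.12, others 1.27 to 1.33), DMSO 24 h replicate 2 (0.99, others 1.19 to 1.20) and TCDD 12 h replicate 4 (1.54, others 1.07 to 1.13).

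The effect of TCDD differed between times for 836 genes. In 100 draws of 4 and 4 arrays at each time, the real grouping included, only the real one gave as many (value 1), and the highest other count was 127. These draws ignore the pairing by day and also remove any TCDD effect shared by all times. They therefore cannot decide whether the effect differed between times. The interaction was called for Xbp1 (adjusted p = 5.13e-09), Mgat4a (8.06e-08), Stx5a, St8sia4 and Cyb561a3 (2.05e-07 each), Prdm1 (0.00121) and Cyp1a1 (0.00194). By list, the TCDD effect at 48 h minus that at 8 h had a median of -0.33 for the plasma cell programme, -0.31 for the unfolded protein response and secretion, 0.22 for G1/S and DNA replication and 0.23 for MYC and ribosome biogenesis; all 4 were also called with an estimated correlation. Outside the gene table, 195 probe sets without a single gene symbol were called with TCDD at 1 or more of the times.

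Interferon response genes rose with TCDD most at 24 h. A single day was argued against: the lowest of the 4 same-day differences of the list mean was 2.01, with a mean of 2.40. In vehicle cells 10 of 19 members were higher at 8 h, 12 at 36 h and 14 at 48 h (10, 15 and 14 adjusted over the list alone), although the list was not called there with an estimated correlation (adjusted p = 0.0914, 0.0744 and 0.111). The list mean was 8.49 in untreated cells, 9.47 in vehicle cells at 8 h and 9.77 at 48 h, and TCDD might have brought the late part of that course forward. The list mean with TCDD at 24 h lay 1.54 above the highest vehicle mean, that at 48 h, with all 4 arrays above all 4. This argues against an earlier arrival at the vehicle levels measured up to 48 h. The vehicle mean was highest at the last time measured (9.56 at 36 h and 9.77 at 48 h). Later vehicle levels were not measured, so an earlier arrival at such a level stays open. Which step links TCDD to these genes was not tested, so a biological response stays a hypothesis.

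AhR targets rose in vehicle cells at 8 h. Mixing of TCDD RNA into vehicle samples would need the same share for each target. Cyp1b1 needed 29.2% and Cyp1a1 2.11% on average, and on each day the share for Cyp1b1 was at least 8.12 times that for Cyp1a1. On another probe set of Cyp1b1 that TCDD raised the share was 12.7%, and the lowest daily ratio was 0.782; Ahrr and Tiparp needed 10.5% and 12.1%. The probe sets differ, so mixing and a response of the vehicle cells cannot be told apart. A wider response like that to TCDD could be present: the 183 other genes higher with TCDD at 24, 36 and 48 h had a median vehicle change of 0.11 at 8 h, at percentile 100 of 10000 expression-matched lists. Of these genes 60 rose and 45 fell. The median was -0.037 at 12 h, when the AhR target list was still higher (adjusted p = 0.00626), and -0.18 at 24 h. The matching does not account for genes that LPS itself moves, so a response to LPS and one to a ligand in the medium stay open too.

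Csf1r, a gene of myeloid cells, and Gzma, one of NK cells, rose with TCDD at 24 h. Cells of another type could bring them, although CH12.LX is a cell line. The 9 other measured markers of T, NK and myeloid cells had a median change of 0.38 at 24 h, between -0.14 and 0.94, which neither reaches the change of Csf1r (1.69) nor stays near 0. By list the median was 0.68 for 4 myeloid markers (0.22 to 0.94), 0.25 for 4 T cell markers and 0.36 for 1 NK cell marker. The abundant transcripts Lyz2, S100a8, S100a9, Cd3d and Cd4 stayed below the filter of 6.21, with highest group means of 6.08, 4.98, 5.07, 5.97 and 4.86. Itgam (5.80), Csf3r (5.78), Ncr1 (5.43), Klrd1 (5.41) and Tcra (5.21) stayed below it too. Cd14 (6.62), Cd3g (6.58) and Cd3e (6.39) lay just above the filter. Some other markers of these lists lay well above it, among them Cd2 (11.05), Fcgr3 (10.75), Cd68 (10.67), Cd8a (9.38), Adgre1 (9.21) and Prf1 (8.76). Induction in the B cells and a small admixture cannot be told apart, because the other markers moved by amounts between these 2 cases.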

How the results depend on the processing

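Of the alternatives, leaving out the 4 arrays standing apart was chosen after seeing the data; the others were fixed before the data were examined. Of 270 alternative values of the main results, 221 stayed within the limits set for them and 49 moved. With the replicate as a fixed block TCDD changed 1004, 1950, 1625, 1307 and 1870 genes at 8, 12, 24, 36 and 48 h, and with a random block 937, 1829, 1497, 1204 and 1775; the effect differed between times for 1915 and 1719 genes. These fits remove differences between days. With only the arrays of the groups compared, which leaves fewer arrays for the spread, TCDD changed 312, 401, 437 and 311 genes at 8, 12, 36 and 48 h, and the vehicle counts were 1518, 1310, 1214, 2063 and 3443. With all probe sets, which tests more features, the vehicle counts were 5242, 5394, 4225, 6504 and 9481.

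Leaving out 1 array or 1 day gave 236 to 430 genes for TCDD at 8 h, 509 to 1022 at 12 h, 483 to 813 at 24 h, 282 to 627 at 36 h and 451 to 1043 at 48 h. The vehicle counts ran from 2122 to 2808, 2091 to 2870, 1620 to 2437, 2732 to 3886 and 4317 to 5222. Leaving out 1 day gave 255 to 516 genes for the difference between times, for which single arrays were not left out. Fewer arrays enter these fits, so a lower count or a lost call does not show that the array or day left out carried the effect. The correlation of the TCDD effect with the vehicle course ran from -0.32 to -0.20 with 1 day left out. It was -0.14 for vehicle cells at 24 h against TCDD at 36 h, -0.14 within 8 h and -0.37 within 48 h with the vehicle arrays split, -0.14 over all genes and -0.33 without the 4 arrays standing apart; the cause was not tested.

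Of 308 called values of genes under the naming rule, with list members of vehicle cells at 8, 24 and 48 h, 308 stayed called with the replicate block, 299 on the values as deposited and 292 without the 4 arrays standing apart. With 1 day left out 1056 of 1232 did, and on a gene's other probe sets 139 of 312. Signs reversed on other probe sets, most of them uncalled, and the cause was not tested. Under TCDD these were Bach2 at 12 h (-0.081) and 36 h (-0.041), Sdc1 at 12 h (0.16), Cyp1b1 at 24 h (-0.56), Slfn1 at 12 h (-0.40) and 48 h (-0.53), and at 24 h Cd37 (0.37), Zpbp2 (0.25), Aurka (0.17), Tpx2 (0.19) and Pes1 (0.026). Nek2 at 36 h (-0.20), Fkbp11 at 48 h (0.20) and Sel1l at 48 h (0.37) reversed too. In vehicle cells they were Cyp1b1 at 8 h (-0.10), 12 h (-0.60) and 24 h (-0.18 and -0.35), Sdc1 at 8 h (-1.49), Ahr at 12 h (0.89), Bach2 at 12 h (0.10), Nfkbiz at 8 h (-0.40) and 48 h (-0.93), Tgfbr1 at 8 h (0.28 and 0.49) and 48 h (0.041), Aff3 at 48 h (0.20) and Tyms at 48 h (0.45, 0.19 and 0.16). At 24 h they were also Aurka (-0.11), Bub1b (-0.11), Nek2 (-0.059), Hmgcs1 (0.082), Tgfbr1 (0.55 and 0.47) and Tgfbr2 (0.094). Of these Sdc1 at 8 h, Ahr at 12 h and Nfkbiz at 48 h were called on the other probe set. On the values as deposited another probe set of Tyms became the highest, and its change was 0.19. Dim genes lie close to the lowest possible value, which limits the changes they can show.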

Other observations

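Other groupings of the same arrays were tried for each count. For TCDD the real grouping was the only one of 35 (value 1) to give as many genes at each of the 5 times. The highest other counts were 2, 170, 0, 7 and 34 at 8, 12, 24, 36 and 48 h, and among the 8 groupings that part all 4 same-day pairs they were 2, 5, 0, 0 and 3. For vehicle cells the real grouping was again the only one, with highest other counts of 619, 1599, 212, 1494 and 2402, and of 47, 45, 5, 183 and 1388 among the groupings that part the pairs. For these 10 counts the real grouping was 1 of 35, a share under 0.05, when the pairing by day is ignored. The 8 groupings that part the pairs are too few to reach such a share, so chance within the pairing was not excluded. Chance cannot be excluded either for the correlation of -0.24 between the vehicle course and the TCDD effect: 5 of 35 groupings gave one as large, and the largest other was 0.38 in size.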
